A study of Mus musculus with 24 samples.

How the data were processed

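The series holds 24 Affymetrix mouse gene arrays, 1 per sample, of inguinal adipose tissue. The samples form 8 groups of 3 biological replicates: mice that carry aP2-Cre and floxed Bmal1 alleles (knockout) and mice with floxed alleles alone (control), each at circadian times CT0, CT6, CT12 and CT18. The control mice carry no Cre recombinase, so an effect of Cre itself is not separated from an effect of the deletion. Per the labels' protocols, RNA was extracted with Trizol, and 50 ng was amplified, fragmented and labelled with biotin before hybridization.

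The deposited table holds log2 expression values that the authors made with RMA (robust multi-array average), per the submitters' processing notes. The RMA version, the annotation behind the probe sets, the scanner settings and the dates of hybridization are not given in the sources used here. The values were used as deposited, with no further normalization. An array has no sequencing depth, and the number of arrays limits the precision. The median over the tested genes lay between 6.46 and 6.56 on all 24 arrays, and the lowest correlation of an array with another of its group lay between 0.980 and 0.992.

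Probe sets were named from the platform annotation supplied with the data, and symbols were compared through Entrez gene numbers with a RefSeq gene table of assembly GRCm38.p6, which was used for names only. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were unnamed here. The Entrez number of 21698 of the named probe sets matched, and 0 symbols changed. A gene was represented by the probe set with the highest mean over all arrays where it had several, as 999 genes did, which left 19938 genes. No filter on dim genes was applied, and no gene was named from a probe set with several symbols.

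A linear model of the 8 groups was fitted to each gene over all 24 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The model had 16 residual degrees of freedom, and the empirical Bayes step added 5.03 prior ones. The contrasts were the mean genotype difference over the 4 times, the genotype difference at each time, CT12 minus CT0 and CT18 minus CT6 in each genotype, and F tests of genotype at any time, of time within each genotype and of the genotype by time interaction. All log2 differences by genotype are knockout minus control, and the error given with a log2 difference is the standard error (SE) of the limma fit. Adjusted p-values come from limma unless another test is named. The amplitude of a gene is that of the 24 h cosine through its 4 group means. Amplitudes of the clock genes other than Arntl were compared by the mean log2 ratio of knockout to control, with a two-sided exact permutation test over 160000 exchanges of the genotype labels within circadian times, in Python 3.11.15. With 4 times over a single cycle, rhythmicity cannot be separated from any other change over the day.

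The contrasts, the gene lists, the rule for the genes named and most alternatives were fixed before the data were examined. Of 34 lists of pathway and cell type genes, 33 were tested with limma's camera (preset inter-gene correlation of 0.01, lists of at least 3 measured genes), with adjustment over the lists of a family. The remaining list, of sex genes, was a check. For each list the number of members past the threshold is also given adjusted over the list alone. The clock gene list had 17 measured members, and its other members are not reported here. Several lists share members, such as the clock genes and their E-box targets. Lists of liver, uterine epithelium, mesothelium and subcutaneous patterning genes were added after the data were seen, and they describe single arrays or the spread between arrays only.

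The genes named are the clock genes, up to 10 genes with the largest rise and fall among those past the threshold and of one sign at all 4 times for the mean genotype difference, and up to 5 in each direction at each time. They are also the 10 with the largest cosine amplitude in each genotype, the 10 with the smallest interaction p, and up to 4 members with the smallest p, with every member that passes, of a list described. Where fewer than 5 genes passed, the 3 with the smallest p in each direction are given as not passing. Symbols of predicted genes and clone-based names were counted and not named. Genes named outside this rule are said to be so.

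The fits were tested on simulated data with each gene's real mean over all arrays and its residual spread. In these data 67 genes were changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. For the mean genotype difference, 94% of genes changed by 0.5 were recovered, 98.5% of those changed by 1 and 100% of those changed by 2, among 19938 genes. For the interaction, where the size was the peak to trough height of a cosine added to the knockout arrays, the shares were 11.9%, 74.6% and 98.5%. The Benjamini-Hochberg adjustment is more lenient when many genes change, as they did in these simulated data. Where few genes change, these shares can overstate what the fits would find. Camera recovered 3 of 3 shifted lists for the mean genotype difference and called 0 others. The simulated genes varied independently, so this could not show false calls that come from genes varying together. Random regroupings of the real arrays by genotype called a median of 8 lists and at most 18. The amplitude ratio was tested on separate simulated data, in which 16 genes shared the same mean, control amplitude and spread. There a log2 ratio of -1.0 was estimated at -1.03. Real amplitudes in control fat lay between 0.11 for Rora and 1.27 for Nr1d1, so this does not show how well the ratio is estimated for genes of small amplitude.

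The alternatives were a filter on dim genes (below the 40th percentile), the mean over probe sets, all probe sets, quantile normalization again, centring on the median, a trended and robust variance, and array weights. They were also fits of the compared groups alone, replicate number as a block, marker means as covariates, other thresholds (adjusted p under 0.10, an absolute log2 change of at least 0.5), a cosine test, estimated inter-gene correlation, fry, and leaving out each array in turn. Fits without the 3 arrays with the highest liver or epithelium marker means, without 4 arrays on the side of the other genotype, with liver or adipocyte marker means as covariates, and of the genotype difference of list changes over time were chosen after seeing the data. For each count of genes or lists, the arrays were also regrouped into 100 random splits, or all 10 where 3 arrays stood against 3.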

Results

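Gene expression was measured over circadian time in inguinal fat, a subcutaneous depot, of mice lacking Bmal1 in adipocytes. Bmal1, whose gene symbol is Arntl, is the partner of CLOCK in the transcription factor that drives the molecular clock. The aP2 promoter was used to direct Cre recombinase to adipocytes, and whether other cells of the pad also recombined was not measured here. All mice were on a C57BL/6J background of at least 6 generations and fed chow. Constant darkness started 36 h before collection, and each group was fasted for 24 h. The 24 arrays cover 8 groups of 3 animals: knockout and control at CT0, the start of the subjective day, CT6, CT12 and CT18. Xist, the RNA of the inactive X chromosome, lay between 10.6 and 10.8 on all 24 arrays, and the Y-linked genes Eif2s3y, Kdm5d and Uty lay at 4.61 or below.

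Arntl, the targeted gene (probe set 10556463), was measured first. In control fat it was highest at CT0, with a mean log2 expression of 7.97 ± 0.0025 (SD, n = 3), and lay at 6.73 ± 0.16 at CT6, 6.34 ± 0.37 at CT12 and 7.32 ± 0.26 at CT18. In knockout fat it lay at 7.43 ± 0.12, 6.95 ± 0.11, 6.74 ± 0.25 and 7.26 ± 0.18 at the same times. At CT0 the control arrays read 7.97 on all of replicates 1, 2 and 3, and the knockout arrays 7.51, 7.30 and 7.49. At CT6 the controls read 6.82, 6.82 and 6.54 and the knockouts 7.08, 6.90 and 6.88. At CT12 the controls read 6.75, 6.04 and 6.22 and the knockouts 6.46, 6.89 and 6.87, and at CT18 the controls read 7.04, 7.38 and 7.55 and the knockouts 7.43, 7.29 and 7.07. The genotype difference was -0.54 ± 0.16 (SE) at CT0, 0.23 ± 0.16 at CT6, 0.40 ± 0.16 at CT12, -0.06 ± 0.16 at CT18 and 0.01 ± 0.08 on average. The difference at CT0 passed when adjusted over the list alone (adjusted p = 0.0434) and not over all genes (adjusted p = 0.633). The labels do not give the deleted exons and whether the probe set lies inside them is not known here, so these values cannot check the deletion. Cells that do not express the recombinase also contribute Arntl RNA to the pad.

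The clock genes differed by genotype in opposite directions. Nr1d1, which encodes the repressor REV-ERB alpha and is a direct target of BMAL1, was lower in knockout fat by genotype mean, with a log2 difference of -0.48 ± 0.08 (SE, adjusted p = 0.0438). All 12 knockout arrays lay below the control mean of their time. Nr1d2, which encodes the related REV-ERB beta, was lower by -0.31 ± 0.08, and the period gene Per3 by -0.27 ± 0.08. The repressor genes Cry1 and Nfil3, both known to be repressed by REV-ERB proteins, were higher by 0.26 ± 0.06 and 0.47 ± 0.13. At CT6, the trough of Cry1 in control fat, Cry1 read 6.87 ± 0.063 (SD, n = 3) in controls and 7.42 ± 0.071 in knockouts, and Nfil3 read 6.81 ± 0.24 and 7.61 ± 0.30. Of the 17 clock genes, 1 (Nr1d1) passed over all genes, and 5 (Nr1d1, Nr1d2, Per3, Cry1 and Nfil3) passed when adjusted over the list alone. The adjusted p over the list was 8.91e-05 for Nr1d1, 0.00607 for Nr1d2, Cry1 and Nfil3, and 0.0122 for Per3. Clock (0.17 ± 0.07), Per1 (-0.17 ± 0.07), Dbp (-0.16 ± 0.08), Hlf (-0.14 ± 0.07), Tef (-0.09 ± 0.05), Bhlhe40 (-0.08 ± 0.06) did not pass either way. Nor did Per2 (0.05 ± 0.05), Cry2 (0.04 ± 0.05), Rora (-0.04 ± 0.07), Bhlhe41 (0.09 ± 0.17) and Ciart (-0.01 ± 0.11).

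**Figure D1:**
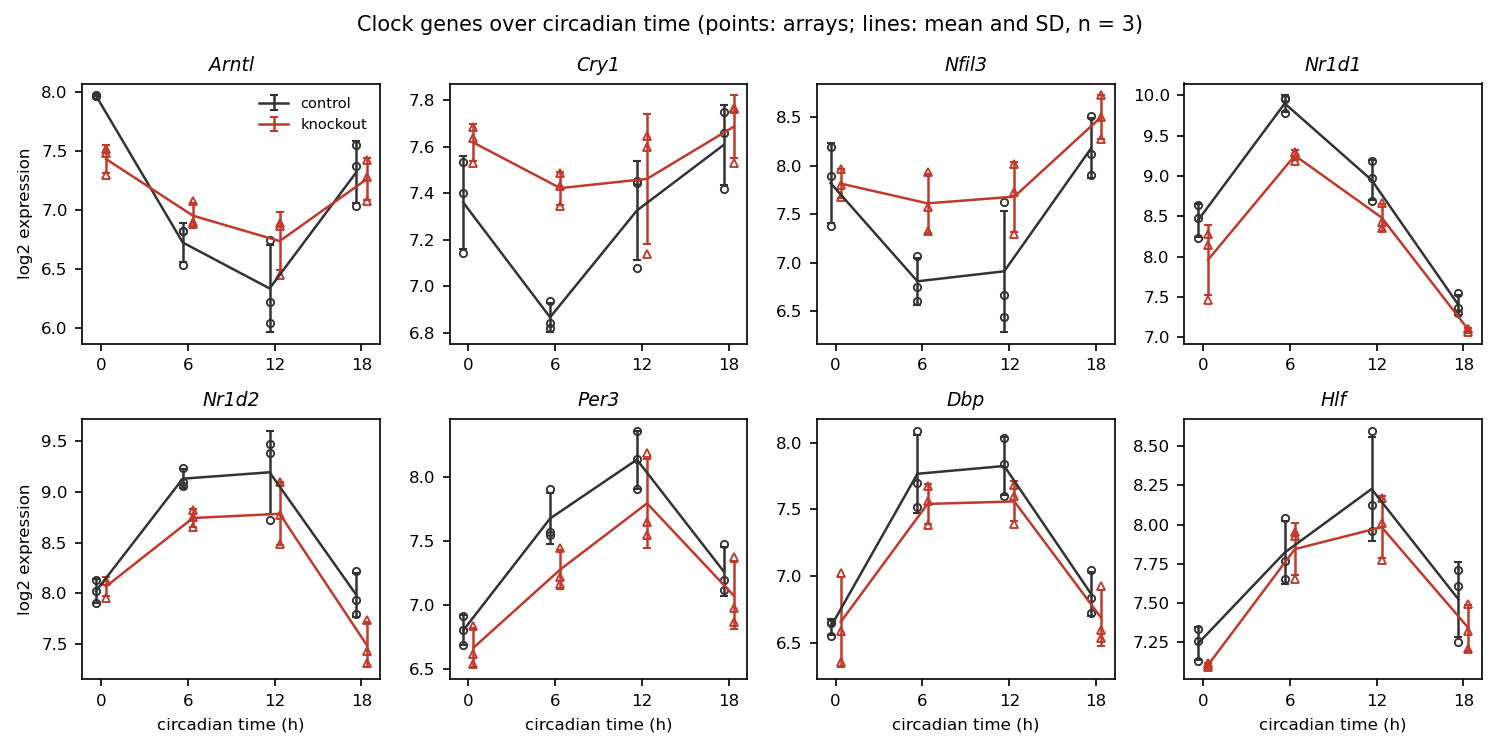
Log2 expression (vertical axis) of 8 clock genes against circadian time in hours (horizontal axis), with an open symbol per array and lines through the group means with SD (n = 3), control in black circles and knockout in red triangles. Arntl in controls spans 7.97 at CT0 to 6.34 at CT12, and Nr1d1 in knockouts lies below controls at all 4 times.

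E-box targets of the clock (13 genes, among them Nr1d1, Per3, Nr1d2 and Per1) were lower in knockout fat as a group, with 10 of 13 members negative and a median log2 difference of -0.14 (camera adjusted p = 6.93e-05). The group call was lost with the correlation estimated from the data (adjusted p = 0.268 with an estimated correlation). The 4 genes known to be repressed by REV-ERB (Cry1, Nfil3, Clock and Arntl) were higher as a group, with a median of 0.21 (camera adjusted p = 0.000196), and adjusted p = 0.159 with an estimated correlation. Adjusted over the list alone, 3 members of each list passed: Nr1d1, Nr1d2 and Per3 fell among the E-box targets, and Cry1, Nfil3 and Clock rose among the REV-ERB targets.

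Outside the clock, the mean genotype difference passed for 3 genes of xenobiotic and lipid ester metabolism, all lower in knockout fat. Ces1d (probe set 10580635), a carboxylesterase with triacylglycerol hydrolase activity, fell by 0.62 on the log2 scale (SE 0.11). Its paralogue Ces1f (probe set 10580663) fell by 0.56 (SE 0.10), and the flavin monooxygenase gene Fmo1 (probe set 10359571) fell by 0.58 (SE 0.10), each with adjusted p = 0.0438. Knockout arrays lay below the control mean of their time for Ces1d on 10 of 12, for Ces1f on 11 of 12 and for Fmo1 on 10 of 12, with knockout replicate 1 at CT12 above it for all 3 genes and knockout replicate 3 at CT18 above it for Ces1d and Fmo1. At CT0 the differences were -1.06 ± 0.21 for Ces1d, -1.08 ± 0.19 for Ces1f and -1.09 ± 0.20 for Fmo1, and at CT18 they were -0.34 ± 0.21, -0.25 ± 0.19 and -0.24 ± 0.20. Without the replicate 3 arrays at CT18 and the replicate 1 arrays at CT12, a choice made after seeing the data, the differences at CT18 were -0.63 ± 0.12, -0.32 ± 0.16 and -0.55 ± 0.15. Other members of the Ces1 family (Ces1a, Ces1b, Ces1c, Ces1e and Ces1g), which can share sequence with these probe sets, had differences between -0.09 and 0.06. Their mean levels of 3.75 to 6.02 lay below the median gene level of 6.50, against 10.48 for Ces1d and 9.29 for Ces1f. A lack of change at such levels says little.

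In all, 4 of 19938 genes passed for the mean genotype difference by limma, 0 higher and 4 lower in knockout fat, and 10 had an adjusted p under 0.10. At an unadjusted p under 0.05 there were 1211 genes, 498 higher and 713 lower, against 997 expected by chance. Genes that came closest without passing were the cation channel gene Trpv2 at 0.78 ± 0.15 (adjusted p = 0.0551), Vstm2a at 0.62 ± 0.13 (adjusted p = 0.125) and the phosphate transporter gene Slc34a2 at 0.31 ± 0.06 (adjusted p = 0.135). In the other direction they were the potassium channel gene Kcnj15 at -0.79 ± 0.15, the glutathione transferase gene Gsta3 at -0.72 ± 0.13 and Fam217a at -0.42 ± 0.08, each with adjusted p = 0.0551. The 4 calls sit close to the threshold: with 1 array left out in turn Ces1d, Ces1f and Fmo1 each passed in 5 of 24 fits and Nr1d1 in 6 of 24, and quantile normalization again left 0 genes.

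**Figure D2:**
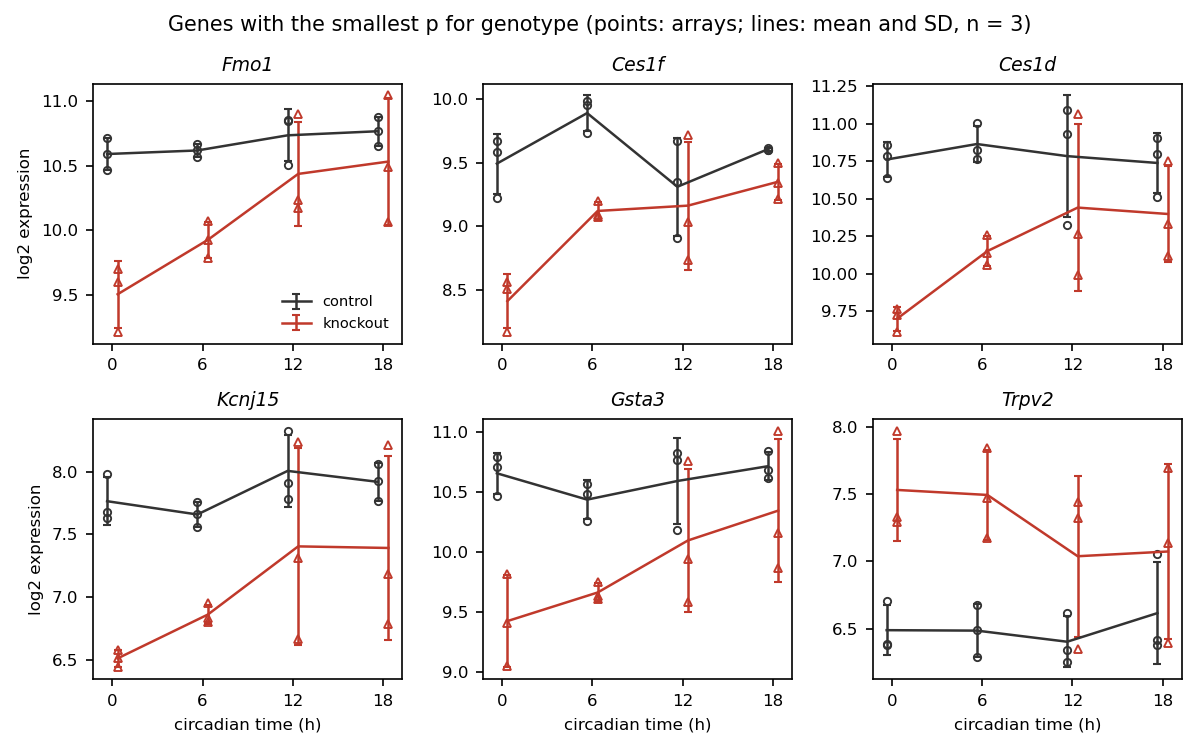
Log2 expression (vertical axis) of Fmo1, Ces1f, Ces1d, Kcnj15, Gsta3 and Trpv2 against circadian time in hours (horizontal axis), with an open symbol per array and lines through the group means with SD (n = 3), control in black circles and knockout in red triangles. The knockout minus control difference of Fmo1 is -1.09 at CT0 and -0.24 at CT18.

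At CT12 and CT18, 4 arrays lay toward the other genotype for most of these genes: replicate 1 of knockout and control at CT12 and replicate 3 of both at CT18. For Ces1d the 2 knockout arrays read 11.06 and 10.75, where the other knockouts of those times read 9.99 to 10.33, and the 2 controls read 10.32 and 10.51, where the other controls read 10.80 to 11.09. For Kcnj15 the 2 knockouts read 8.23 and 8.21 and their same-numbered controls 7.78 and 7.77, and for Trpv2 they read 6.35 and 6.39 against 6.62 and 7.05. The imprinted gene Zim1 read 8.33 and 5.24 in these knockouts and 9.21 and 8.80 in these controls, while at CT0 and CT6 it read 8.88 to 10.39 in knockouts and 6.60 to 8.40 in controls. Zim1 lies outside the rule for named genes and was chosen after its values were seen. Clock genes that passed over the list alone were mixed. Cry1 read 7.14 in the knockout and 7.45 in the control at CT12 and 7.53 and 7.75 at CT18, both reversed. Per3 was reversed too, with 8.19 and 7.90 and then 7.37 and 7.19. Nfil3 (7.30 and 7.62) and Nr1d2 (9.10 and 8.72) were reversed at CT12 only. Other genes kept the order of the labels in these pairs. Nr1d1 read 8.67 in the knockout and 8.69 in the control array at CT12, where the other knockouts read 8.36 and 8.43 and the other controls 9.19 and 8.98. At CT18 it read 7.07 and 7.37. Ampd3 read 7.73 and 7.98 at CT12 and 7.60 and 7.84 at CT18, and Slc34a2 read 5.07 and 4.83 and then 5.46 and 5.36. For Slc34a2 the other knockouts at CT12 read 5.27 and 5.20 and the other controls 5.25 and 5.00. At CT18 its control of the pair lay nearer to the other knockouts (5.39 and 5.48) than to the other controls (4.86 and 4.99). Ces1f kept the order of the labels at CT18, with 9.49 and 9.62, and for Adh1 all knockout arrays lay below all controls at each of the 4 times. A score was taken over 100 genes picked by genotype at CT0 and CT6 alone, with the remaining arrays of a time setting control at 0 and knockout at 1. On it knockout and control lay at -0.17 and 0.78 in the CT12 pair and at -0.21 and 0.56 in the CT18 pair. Of the 20 ways to call 3 of the 6 arrays of a time knockout, the labels ranked 5 at CT12 and 5 at CT18, and the first exchanged these pairs.

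All fits follow the labels, and the genotype results depend on these 4 arrays. Without them 139 genes passed for the mean genotype difference by limma, 56 higher and 83 lower in knockout fat, against 4 with them. This fit was chosen after seeing the data, and since the arrays were singled out by genes that differ by genotype, its p-values overstate the evidence and no further gene is named from it. Without the 4 arrays the mean differences were -0.82 ± 0.05 for Ces1d, -0.70 ± 0.07 for Ces1f, -0.75 ± 0.07 for Fmo1 and -0.54 ± 0.09 for Nr1d1.

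Of the other gene groups, endothelial genes were lower in knockout fat on average over the 4 times. All 12 of 12 members were negative, with a median of -0.16 (camera adjusted p = 7.76e-09, and adjusted p = 0.159 with an estimated correlation). Adjusted over the list alone 5 of them fell, Ptprb by 0.26 (SE 0.09), Cdh5 by 0.24 (SE 0.09), Esam by 0.21 (SE 0.08), Pecam1 by 0.18 (SE 0.07) and Egfl7 by 0.16 (SE 0.06) (none of the 5 over all genes). Glucocorticoid responsive genes were lower with a median of -0.18 and 13 of 14 members negative (camera adjusted p = 2.14e-07, and adjusted p = 0.159 with an estimated correlation). Dusp1, a phosphatase that acts on MAP kinases, passed over the list alone at -0.32 ± 0.07, and Mt2 (-0.41 ± 0.14), Fkbp5 (-0.39 ± 0.16) and Tsc22d3 (-0.19 ± 0.08) did not. T cell markers, which a lymph node in the pad would carry, were lower with a median of -0.12 and 12 of 13 members negative (camera adjusted p = 0.00436, and adjusted p = 0.599 with an estimated correlation). The adipocyte markers had a median of -0.06 (camera adjusted p = 0.0608).

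Genes of de novo lipogenesis and triglyceride synthesis were lower in knockout fat, with 14 of 18 members negative and a median of -0.14 (camera adjusted p = 0.000598, and adjusted p = 0.51 with an estimated correlation). Adjusted over the list alone 3 of them fell: Thrsp, a regulator of lipogenesis, by 0.60 (SE 0.14), Acacb, an acetyl-CoA carboxylase, by 0.37 (SE 0.12), and Lpin1, a phosphatidate phosphatase, by 0.38 (SE 0.13). Adipokine genes had a median of -0.09 with 8 of 10 members negative (camera adjusted p = 0.00436, and adjusted p = 0.159 with an estimated correlation). Rbp4, which encodes a retinol carrier, fell by 0.28 (SE 0.06), Nampt, an enzyme of NAD synthesis, by 0.40 (SE 0.11) and Nrg4, an EGF family ligand, by 0.33 (SE 0.11) when adjusted over the list alone. The cold-inducible RNA binding genes Cirbp (-0.24 ± 0.08) and Rbm3 (-0.09 ± 0.04) also passed over their list alone (list camera adjusted p = 0.00849, and adjusted p = 0.159 with an estimated correlation). Interferon-induced Ifit3 (-0.34 ± 0.10), Ifit2 (-0.21 ± 0.06) and Xaf1 (-0.17 ± 0.06) did so in theirs (list camera adjusted p = 0.00436, and adjusted p = 0.51 with an estimated correlation). Outside the clock lists, no member of these lists passed over all genes. In all, 9 of 33 lists passed for the mean genotype difference by camera and 0 with an estimated correlation or by fry.

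At CT0 genes of lipid synthesis were lower in knockout fat. Thrsp was lower by -1.41 ± 0.28 and was the 1 lipogenesis gene to pass over the list alone. The list had a median of -0.44 with 16 of 18 members negative (camera adjusted p = 3.49e-08, and adjusted p = 0.481 with an estimated correlation). Among fatty acid elongation and desaturation genes Fads1 (-0.64 ± 0.17), Hacd2 (-0.50 ± 0.13), Hsd17b12 (-0.50 ± 0.18), Tecr (-0.43 ± 0.11), Scd1 (-0.39 ± 0.13) and Elovl6 (-1.65 ± 0.61) fell over the list alone. Hacd1 (0.29 ± 0.11) and Elovl4 (0.29 ± 0.11) rose. That list passed downward with a median of -0.10 (camera adjusted p = 0.00116, and adjusted p = 0.256 with an estimated correlation). Cholesterol synthesis genes were lower with a median of -0.18 (camera adjusted p = 9.54e-05, and adjusted p = 0.481 with an estimated correlation). Fdft1 (-0.66 ± 0.20), Fdps (-0.40 ± 0.12) and Nsdhl (-0.69 ± 0.21) passed over the list alone. All 25 respiratory chain genes were negative with a median of -0.19 (camera adjusted p = 6.77e-13, and adjusted p = 0.581 with an estimated correlation). In the same comparison mammary and skin epithelium markers were higher with a median of 0.11 (camera adjusted p = 0.00103, and adjusted p = 0.68 with an estimated correlation). Smooth muscle and pericyte markers were higher with a median of 0.38 (camera adjusted p = 0.00404, and adjusted p = 0.68 with an estimated correlation). Adipocyte markers were lower with a median of -0.10 (camera adjusted p = 0.000798, and adjusted p = 0.68 with an estimated correlation). Macrophage markers were lower with a median of -0.25 and 13 of 14 negative (camera adjusted p = 0.000375, and adjusted p = 0.68 with an estimated correlation). Many of these values depend on single arrays, among them replicate 2 of the knockout group, which also carried uterine epithelial transcripts. Without it the medians were 0.02 for adipocyte markers and 0.01 for macrophage markers, which both turned direction, -0.08 for respiratory chain genes, 0.02 for mammary and skin epithelium, 0.19 for smooth muscle and pericyte, -0.16 for lipogenesis and -0.09 for cholesterol synthesis. Without control replicate 2 they were -0.17 for lipogenesis, -0.10 for cholesterol synthesis, -0.03 for elongation and desaturation and 0.67 for smooth muscle and pericyte. Without control replicate 1 the last was 0.15, without control replicate 3 it was 0.23 and cholesterol synthesis -0.29, and without knockout replicate 3 elongation and desaturation was -0.01. The macrophage median was -0.40 without knockout replicate 3 and -0.12 without control replicate 3.

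At single genes the 4 times gave few calls. At CT18 Kir3dl2 (probe set 10606870), a receptor gene of natural killer and T cells, was higher in knockout fat by 0.52 ± 0.08 (SE, adjusted p = 0.0341), the 1 gene that passed. Its group means of 3.97 ± 0.08 (SD, n = 3) and 4.49 ± 0.08 lay below the median gene level of 6.50, and it passed in 8 of 24 fits with 1 array left out and not without the 4 arrays on the other genotype's side (adjusted p = 0.116). By limma 0 genes passed at CT0, CT6 and CT12, with 1106, 752 and 497 genes at an unadjusted p under 0.05, and 0 passed for genotype at any time, with 783. At CT0 Ces1f, Fmo1 and Ces1d had the smallest p among lower genes (adjusted p = 0.165, 0.165 and 0.318), and Atp11a (0.42 ± 0.09), Casc3 (0.30 ± 0.07) and Pdlim1 (0.42 ± 0.10) among higher ones. At CT6 Cry1 (0.56 ± 0.13), Zfp668 (0.31 ± 0.08) and Bend6 (0.40 ± 0.10) led the higher genes and Ofcc1 (-0.46 ± 0.11), Taf8 (-0.29 ± 0.07) and Nr1d1 (-0.65 ± 0.16) the lower ones. At CT12 Hspb9 (0.28 ± 0.07), Kctd21 (0.44 ± 0.11) and Ms4a6d (0.80 ± 0.22) stood against Ampd3 (-0.28 ± 0.08), Rnf152 (-0.36 ± 0.11) and Zfp385b (-0.31 ± 0.09). At CT18 Spopfm2 (0.42 ± 0.08), Hspa1l (0.56 ± 0.12) and Skint7 (0.33 ± 0.08) stood against Taf5l (-0.48 ± 0.09), Clec5a (-0.44 ± 0.10) and Parp11 (-0.49 ± 0.11), none of which passed.

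At the later times clock targets, immune markers and stromal genes also differed by camera. At CT6 the REV-ERB repressed genes had a median of 0.39, and Nfil3 (0.80 ± 0.26) and Cry1 (0.56 ± 0.13) passed over the list alone (camera adjusted p = 3.22e-05, and adjusted p = 0.328 with an estimated correlation). Immediate early genes had a median of -0.13, and Btg2 (-0.35 ± 0.10), Zfp36 (-0.32 ± 0.10) and Dusp1 (-0.46 ± 0.15) passed over the list alone (camera adjusted p = 0.000591, and adjusted p = 0.328 with an estimated correlation). At CT6 B cell markers were lower with a median of -0.32 (camera adjusted p = 0.000798, and adjusted p = 0.68 with an estimated correlation). At CT12 Arntl (0.40 ± 0.16) and Nfil3 (0.77 ± 0.26) passed over the REV-ERB list alone (camera adjusted p = 9.54e-05, and adjusted p = 0.328 with an estimated correlation). Extracellular matrix genes had a median of -0.15 at CT12 with all 19 negative (camera adjusted p = 0.0025, and adjusted p = 0.68 with an estimated correlation), and a median of -0.04 without control replicate 1 and -0.08 without knockout replicate 2. Other stromal markers had the same sign at CT12: endothelial with a median of -0.21 and 12 of 12 negative (camera adjusted p = 1.17e-05, and adjusted p = 0.648 with an estimated correlation), smooth muscle and pericyte with -0.25 and 10 of 10 (camera adjusted p = 0.000375, and adjusted p = 0.581 with an estimated correlation). The endothelial median was -0.13 without knockout replicate 2 and -0.32 without knockout replicate 3. Adipose progenitor and fibroblast markers had a median of -0.12 with 11 of 11 negative and did not pass (camera adjusted p = 0.0559). Macrophage markers had a median of 0.23 at CT12 (camera adjusted p = 9.54e-05) and of -0.25 at CT18 (camera adjusted p = 0.00145), with adjusted p = 0.68 and 0.687 with an estimated correlation. Without knockout replicate 2 at CT12 their median was 0.14, and at CT18 it was -0.09 without control replicate 2, -0.11 without knockout replicate 3 and -0.38 without control replicate 3. Over the 4 times 39 of 132 list tests passed by camera and 0 with an estimated correlation. Across genes, which are not independent replicates, the genotype differences at 2 times correlated with r between 0.00597 (CT12 and CT18) and 0.211 (CT6 and CT18).

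The interaction asks whether the time course differed between genotypes. By limma 0 genes passed over all genes, with 595 at an unadjusted p under 0.05 against 997 expected. Of the clock genes, Arntl passed when adjusted over the list alone (unadjusted p = 0.00218, adjusted p = 0.0371) and not over all genes (adjusted p = 1). The call held in 10 of 24 fits with 1 array left out. The smallest unadjusted p belonged to Kir3dl2 (8.75e-05), Taf5l (0.000365), Asnsd1 (0.000809), Hspa1l (0.00095), Atp11a (0.0017), Clpp (0.00184), Lonrf3 (0.00213), Arntl (0.00218), Pcdhb2 (0.00229) and Rdh18-ps (0.00237). For Fmo1, Ces1f and Ces1d, whose differences were largest at CT0, the unadjusted interaction p was 0.0201, 0.00776 and 0.0732. Without the 4 arrays on the other genotype's side these were 0.0461, 0.0133 and 0.0418.

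The amplitude of the clock was compared directly. Arntl had an amplitude of 0.87 in control fat and 0.38 in knockout fat, with fitted peaks at 22.7 and 22.4 h. Without Arntl, 14 of 16 clock genes had the smaller amplitude in knockout fat and 2 (Per1 and Per2) the larger. Cry1 went from 0.37 to 0.15, Nfil3 from 0.82 to 0.45 and Ciart from 0.31 to 0.12. Nr1d1 went from 1.27 to 1.11, Nr1d2 from 0.82 to 0.72, Dbp from 0.75 to 0.62, Per3 from 0.70 to 0.57 and Hlf from 0.52 to 0.51. Fitted peaks of Nr1d1 (6.8 and 6.9 h), Dbp (9.6 and 9.1 h) and Per3 (10.9 and 11.3 h) were within 0.5 h of each other in control and knockout fat. Those of Ciart, Cry2, Bhlhe40 and Nfil3 lay 3.1, 2.5, 2.2 and 1.6 h earlier in knockout fat and that of Cry1 1.8 h later, and no test of the peaks was made. Ciart, Cry2, Bhlhe40 and Cry1 did not vary over time in knockout fat even over the list alone (limma adjusted p = 0.767, 0.382, 0.261 and 0.235). Their fitted peaks there carry little weight. The mean log2 ratio of amplitudes was -0.45, a ratio of 0.733, and the exact two-sided permutation test did not pass (p = 0.173). Without the 3 arrays with the highest liver or epithelium marker means, a choice made after seeing the data, the ratio was -0.66 (exact permutation p = 0.0299). No other alternative passed: exact permutation p lay between 0.0543 and 0.321, with -0.62 (p = 0.115) without the 4 arrays on the other genotype's side and -0.34 (p = 0.312) after quantile normalization again.

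In control fat 12 genes varied over circadian time by limma, 6 of them in the clock list. Nr1d1 (adjusted p = 1.06e-07), Arntl (5.38e-05), Nr1d2 (0.00031), Dbp (0.000511), Per3 (0.00181) and Hlf (0.0214) are transcription factors and a period gene of the clock, and 12 of 17 clock genes passed when adjusted over the list alone. The other 6 were Pfkfb3, a regulator of glycolysis, with an amplitude of 0.61, the taurine transporter gene Slc6a6 with 0.47, Lonrf3 with 0.44, Tns2 with 0.38, the receptor kinase gene Kit, a mast cell marker here, with 0.34, and Zfp622 with 0.22. Pfkfb3 had a mean of 10.90 ± 0.12 (SD, n = 3) at CT6 and 9.69 ± 0.21 at CT18. Slc6a6 had 9.17 ± 0.04 at CT6 and 8.28 ± 0.07 at CT18. By single contrasts 8 genes passed for CT12 minus CT0, 6 higher and 2 lower, led by Per3 (1.33 ± 0.16), Dbp (1.21 ± 0.16), Nr1d2 (1.17 ± 0.17) and Arntl (-1.63 ± 0.16). A further 12 passed for CT18 minus CT6, 3 higher and 9 lower, led by Nfil3 (1.37 ± 0.26), Cry1 (0.74 ± 0.13) and Nr1d1 (-2.50 ± 0.16). Without the 3 arrays with the highest liver or epithelium means 25 genes passed for time in control, and without the 4 arrays on the other genotype's side 24.

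In knockout fat 14 genes varied over circadian time. Nr1d1 (adjusted p = 1.4e-06), Nr1d2 (0.00202), Dbp (0.0119), Per3 (0.02) and Hlf (0.0254) passed. Arntl did not over all genes (adjusted p = 0.149) and did over the list alone (adjusted p = 0.00263), where 11 of 17 clock genes passed. Cybrd1, a ferric reductase gene, had an amplitude of 0.50, Cys1 of 0.48, the lipocalin gene Apod of 0.43, and Slc6a6 of 0.40. The amplitude was 0.37 for the chemokine gene Ccl11, 0.26 for the lipid flippase gene Atp11a, 0.25 for Art3, 0.17 for Snx1 and 0.13 for Lemd3. Dbp, Hlf, Nr1d1, Nr1d2, Per3 and Slc6a6 were the 6 genes that passed in both genotypes. For CT12 minus CT0, 19 genes passed, 15 higher and 4 lower, led by the interferon-inducible genes Ifi205 (1.28 ± 0.21) and Ifi207 (1.25 ± 0.22) and by Per3 (1.13 ± 0.16). For CT18 minus CT6 4 genes passed, all lower: Nr1d1 (-2.16 ± 0.16), Nr1d2 (-1.25 ± 0.17), Slc6a6 (-0.79 ± 0.11) and Cybrd1. With 1 array left out, the count ranged from 0 to 63 for CT12 minus CT0 and from 3 to 115 for CT18 minus CT6, the last without knockout replicate 2 at CT18. The mean of Cybrd1 was 7.77 ± 0.23 (SD, n = 3) at CT6 and 6.77 ± 0.26 at CT18. The genes named for these single contrasts, in control and knockout fat, lie in part outside the rule for named genes and were chosen after their values were seen. Across genes, r between the genotypes was 0.333 for CT12 minus CT0 and 0.439 for CT18 minus CT6. Without the 3 arrays with the highest liver or epithelium means 5 genes passed for time in knockout and 6 for CT12 minus CT0, and without the 4 arrays on the other genotype's side 4 and 3.

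As groups, E-box targets rose from CT0 to CT12 in control fat by a median of 0.59 with 13 of 13 members positive (camera adjusted p = 1.23e-28, and adjusted p = 0.00558 with an estimated correlation). In knockout fat the median was 0.59 (camera adjusted p = 1.91e-16, and adjusted p = 0.0737 with an estimated correlation). REV-ERB repressed genes had a median of -0.60 from CT0 to CT12 in control fat (camera adjusted p = 9.78e-09, and adjusted p = 0.0263 with an estimated correlation). In knockout fat the median was -0.15 (camera adjusted p = 0.0211, and adjusted p = 0.416 with an estimated correlation), and -0.02 without replicate 1 and -0.27 without replicate 3 at CT12. The difference between genotypes in that change had a median of 0.45 (camera adjusted p = 0.0064, and adjusted p = 0.46 with an estimated correlation), in a test chosen after seeing the data. From CT6 to CT18 in control fat the REV-ERB genes rose by a median of 0.67 (camera adjusted p = 9.07e-07, and adjusted p = 0.0455 with an estimated correlation). Fatty acid elongation genes had a median of -0.10 from CT0 to CT12 in control fat (camera adjusted p = 0.000661, and adjusted p = 0.0263 with an estimated correlation), with Elovl6 at -1.56 ± 0.61. That median was -0.06 without control replicate 2 at CT0 and -0.05 without control replicate 3. Pparg, the regulator of adipocyte differentiation, and Klf15, a glucocorticoid-induced factor, rose from CT0 to CT12 over their list alone in control fat (0.54 ± 0.14 each) and in knockout fat (0.55 ± 0.14 and 0.54 ± 0.14). That list, of adipogenic transcription factors, had camera adjusted p = 0.0134 in control and 0.00973 in knockout, and adjusted p = 0.598 and 0.416 with an estimated correlation.

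Several groups of knockout fat moved from CT0 to CT12 by camera alone. Lipogenesis genes rose with a median of 0.30 (camera adjusted p = 3.86e-05, and adjusted p = 0.416 with an estimated correlation). Gpam (0.76 ± 0.19), Lpin1 (0.91 ± 0.25), Thrsp (0.83 ± 0.28), Dgat1 (0.48 ± 0.17) and Mlxipl (0.46 ± 0.14) passed over the list alone. Extracellular matrix genes fell with a median of -0.29 and 17 of 19 negative (camera adjusted p = 1.16e-08, and adjusted p = 0.169 with an estimated correlation). Of these, 8 collagen and matrix genes passed over the list alone, among them Col5a2 (-0.46 ± 0.09), Col3a1 (-0.54 ± 0.13) and Col1a1 (-0.48 ± 0.13). Glucocorticoid responsive genes rose with a median of 0.36 (camera adjusted p = 5.35e-05, and adjusted p = 0.416 with an estimated correlation). Zbtb16 (0.81 ± 0.21), Fkbp5 (1.02 ± 0.31), Per1 (0.47 ± 0.14), Tsc22d3 (0.44 ± 0.16) and Klf9 (0.34 ± 0.12) passed over the list alone. In the same comparison smooth muscle and pericyte markers fell with a median of -0.66, led by Cnn1 (-2.04 ± 0.43) and Myh11 (-1.48 ± 0.39) (camera adjusted p = 3.22e-07, and adjusted p = 0.163 with an estimated correlation). Macrophage markers rose with a median of 0.47, with Clec10a (0.70 ± 0.22), Cd163 (0.72 ± 0.26) and C1qb (0.52 ± 0.18) passing over the list alone (camera adjusted p = 1.94e-07, and adjusted p = 0.326 with an estimated correlation). Without replicate 2 of the knockout group at CT0 the medians were 0.23 for macrophage markers, 0.11 for lipogenesis, 0.22 for glucocorticoid responsive and -0.45 for extracellular matrix genes, and without replicate 1 of that group it was -0.19 for extracellular matrix genes. In all, 20 of 66 list tests over time passed in control fat and 5 of them with an estimated correlation, against 28 of 66 and 0 in knockout fat. For the genotype difference of these changes, 19 of 66 passed by camera and 0 with an estimated correlation (lowest adjusted p = 0.46).

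Transcripts of other tissues were raised in some arrays. In replicate 2 of the knockout group at CT0, 14 uterine epithelial genes had a median of 1.42 above the other arrays of the group, with Sult1d1 at 5.23, Cxcl15 at 3.85 and Pgr at 3.40. In replicate 2 of the knockout group at CT6, 17 liver genes had a median of 2.30 above the other arrays, with Fabp1 at 5.17, Apoa2 at 4.38 and Alb at 4.23. In replicate 2 of the control group at CT18 the liver genes had a median of 0.65, with Fabp1 at 3.95. They also had a median of 0.55 in replicate 1 of the control group at CT0 and of 0.48 in replicate 1 of the knockout group at CT0. B cell markers ranged from 5.96 to 7.08 among control arrays at CT0 and from 5.81 to 6.95 at CT18.

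**Figure D3:**
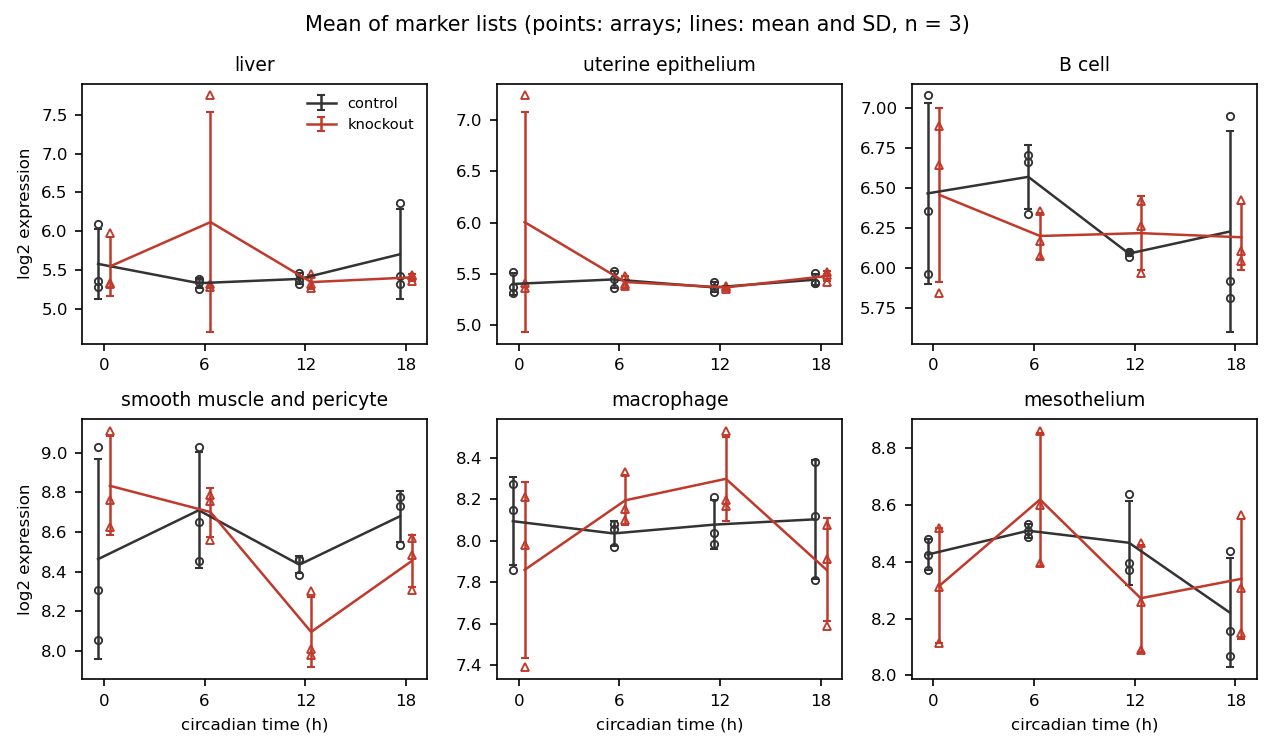
Mean log2 expression (vertical axis) of 6 marker lists against circadian time in hours (horizontal axis), with an open symbol per array and lines through the group means with SD (n = 3), control in black circles and knockout in red triangles. A knockout array reaches 7.75 for the liver list at CT6 and another 7.24 for the uterine epithelium list at CT0.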

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

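The adipocyte share test of the Fmo1 pattern, the tests of the control array at CT18 and of the epithelial genes, all tests of the 4 arrays, and the fits without 3 or 4 arrays were chosen after the result was seen. For the liver genes of the control array at CT18 the lower bound was also set after its value was seen.

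Arntl was singled out because its genotype difference varied with circadian time. The interaction passed when adjusted over the clock list alone (adjusted p = 0.0371) and not over all genes (adjusted p = 1), with -0.54 at CT0 and 0.40 at CT12.

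Outside the named genes, the unnamed probe set 10340345 was lower in knockout fat at CT18 by -1.25 ± 0.19 (SE, adjusted p = 0.047 over all probe sets). Probe sets 10380059, 10380061, 10380063 and 10380065, which have several symbols and identical values, had a difference of -1.16 ± 0.19 (adjusted p = 0.0299) from CT0 to CT12 in knockout fat. The unnamed probe set 10584600 had -0.93 ± 0.16 (adjusted p = 0.0432) in the same contrast. A second probe set of Fabp3, 10508614, had -0.91 ± 0.14 (adjusted p = 0.0418) from CT6 to CT18 in knockout fat.

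Fmo1, Ces1f and Ces1d were lower in knockout pads by -0.59 on average over the 3 genes, and a lower share of adipocytes would move all adipocyte markers by about as much, but their median was -0.0594 (quartiles -0.09 to -0.03). The 3 arrays with the highest liver or epithelium means do not account for it, since without them the mean was -0.56, and the calls ended (adjusted p = 0.161 to 0.175) as the SE of Fmo1 went from 0.10 to 0.11 and that of Ces1d from 0.11 to 0.12 with fewer arrays. Dilution by B and T cells of a lymph node would need more of their RNA in knockout fat, where T cell markers were instead lower. A covariate of the B and T cell means could thus hardly have removed the fall of the 3 genes. With it the mean was -0.58, although the limma adjusted p of 0.0811 no longer passed with fold and SE nearly unmoved. Dilution by other blood cells was not tested. Among 100 splits of the arrays by genotype only the real one gave 4 genes or more, and the highest other gave 2. These splits were drawn at random and do not cover every arrangement. On the score of 100 genes picked at CT0 and CT6 the labels ranked 5 of 20 at CT12 and at CT18. The splits thus do not show that no other arrangement calls as many genes. A lasting effect of the genotype on these genes is a hypothesis that stays open, and hybridization shared between Ces1d and Ces1f was not tested.

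The 3 arrays that stood apart from their groups were tested with a part of the liver genes or with genes that mark a second tissue. The 5 liver genes used belong to the 17 liver genes described above, so they are not an independent check. Liver transcripts Apoc3, Ahsg, Fga, Tat and Itih3 were raised by a median of 0.63 in the knockout array at CT6, which is consistent with liver tissue or liver RNA in that sample. The same genes had a median of 0.18 in the control array at CT18, which leaves liver RNA there undecided. Replicate 1 of the control group at CT0, which was not among the 3 arrays, had a higher median of 0.28 on these genes. In the knockout array at CT0 simple epithelial genes such as Epcam (2.47) and Krt18 (1.94) had a median of 0.97, which is consistent with uterine or another simple epithelium, while basal keratin genes had a median of 0.13, which argues against skin or the basal layer of mammary epithelium. No biological explanation was tested, since the labels give these 3 animals no treatment of their own.

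In 2 pairs of same-numbered arrays, replicate 1 at CT12 and replicate 3 at CT18, the knockout read higher than the control for Ces1d, Fmo1, Gsta3 and Kcnj15 and lower for Trpv2, the reverse of all other pairs. On 100 other genes picked by genotype at CT0 and CT6, where control is 0 and knockout 1, the knockout minus control position was -0.9547 in the CT12 pair and -0.7724 in the CT18 pair, which is consistent with labels exchanged between knockout and control in both. Incomplete recombination in the 2 knockout animals is argued against as the whole cause, since the 2 control arrays, which carry no recombinase by their labels, were out of place as well, at a mean position of 0.6717. A tissue state that varies between animals of a group stays open, since genes picked on the remaining arrays at CT12 and CT18 had a mean signed correlation within groups of 0.2057 at CT0 and CT6, between the bounds set for and against it. Whether labels were exchanged can be settled only by genotyping or sample records, which are not used here. The labelled order was kept in both pairs by Ampd3 (7.73 in the knockout and 7.98 in the control at CT12, 7.60 and 7.84 at CT18) and Adh1, without overlap at any of 4 times. Slc34a2 kept it too (5.07 and 4.83, 5.46 and 5.36), though its control at CT18 lay nearer to the knockouts than to the other controls. Ces1f kept it at CT18 (9.49 and 9.62). Ampd3, Slc34a2 and Ces1f were named from rankings that follow the labels, and Adh1 is given for its order under them. Genes found this way can keep that order in 2 pairs whatever the true labels, so they do not decide against an exchange. The clock genes that passed over the list alone for genotype mean were divided. Nr1d1 kept the labelled order in both pairs (8.67 and 8.69, 7.07 and 7.37), at CT12 by a very small margin. Cry1 and Per3 had the reverse order in both pairs, and Nfil3 and Nr1d2 had it at CT12 and the labelled order at CT18.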

How the results depend on the processing

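The fits without 3 or 4 arrays and with the liver or adipocyte covariate were chosen after seeing the data; the cause of the shifts was not tested except where fewer arrays or genes entered. No gene called by a contrast reversed its direction in any setting, and the F tests over time have no direction to reverse. Of the values for called genes, F tests included, 1090 kept their side of the threshold under another setting and 264 did not. With 1 array left out these numbers were 1409 and 367. The direction of the amplitude ratio, -0.45, also held throughout. The arrays' signal over background was not measured, and their number limits what can be called.

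Counts are of genes past the threshold, in the order named, against 4 for genotype mean, 1 for genotype at CT18, 8 for CT12 minus CT0 in control, and 12 for CT18 minus CT6 in control. In knockout fat they were 19 for CT12 minus CT0 and 4 for CT18 minus CT6, with 12 for time in control, 14 for time in knockout, and 1 clock gene over the list alone for the interaction. With dim genes removed, genotype mean gave 9, CT18 0 and CT18 minus CT6 in knockout 15. Over all probe sets genotype mean gave 0, CT18 2, CT12 minus CT0 in control 5, CT18 minus CT6 in control 5, time in knockout 5 and the clock interaction 0. After quantile normalization again they were 0 for genotype mean, 0 at CT18, 5 for CT12 minus CT0 in control, 13 for CT18 minus CT6 in knockout and 23 for time in knockout. Median centring gave 0 at CT18 and 23 for time in knockout. A trended and robust variance gave 0 for genotype mean. Array weights gave 51 for genotype mean, 0 at CT18, and 73, 49 and 75 for CT12 minus CT0 in control, CT18 minus CT6 in control and CT12 minus CT0 in knockout. They also gave 82 for time in control, 30 for time in knockout and 8 clock genes against 5 for genotype mean over the list alone. Fits of the compared groups alone gave 9 at CT6 against 0, 0 at CT18, 3, 5, 0 and 2 for the 4 time contrasts and 2 for time in knockout.

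With the B and T cell covariate the counts were 0 for genotype mean, 40 for CT12 minus CT0 in knockout and 34 for time in knockout, and with the muscle covariate 2 at CT18. The epithelium covariate gave 10 for genotype mean, 24, 26 and 23 for CT12 minus CT0 in control, CT18 minus CT6 in control and CT18 minus CT6 in knockout, 29 for time in control, 37 for time in knockout and 0 for the clock interaction. At an adjusted p under 0.10, 10 genes passed for genotype mean, 16, 44 and 19 for CT12 minus CT0 in control, CT12 minus CT0 in knockout and CT18 minus CT6 in knockout, 21 for time in control and 65 for time in knockout. The cosine test gave 23 for time in control. With the 3 arrays left out there were 0 at CT18, 17, 24 and 6 for CT12 minus CT0 in control, CT18 minus CT6 in control and CT12 minus CT0 in knockout, 25 for time in control, 5 for time in knockout, and an amplitude ratio of -0.66 that passed, as no other setting did. Without the 4 arrays on the other genotype's side the counts were 139 for genotype mean, 6, 1, 10 and 0 at CT0, CT6, CT12 and CT18, 33 at any time, 17 for CT12 minus CT0 in control and 3 in knockout, 24 for time in control and 4 for time in knockout. Then 10 clock genes passed over the list alone for genotype mean and 3 for the interaction. The liver covariate gave 0 for genotype mean, 0 at CT18 and 0 for the clock interaction. The adipocyte covariate gave 40 for genotype mean, 19, 33, 33 and 60 for the 4 time contrasts, 28 for time in control and 90 for time in knockout. For gene lists, the estimated correlation left 0 of 9 for genotype mean, 0 of 39 at each time, 5 of 20 for time in control and 0 of 28 for time in knockout, and fry left 0, 0, 5 and 6. Beside the counts of 0, limma's unadjusted p lay under 0.05 for 1211 genes for genotype mean and 1206 at CT18.

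Replicate numbers were not taken as pairs, since 5 of 12 pairs of same-numbered arrays deviated together with r over 0.1 (-0.37 to 0.37) and 5 of 12 knockout arrays were closest to their own number. At CT0 alone all 3 pairs lay over 0.1 (0.189, 0.374 and 0.327), each closest to its own number. With the block within time 13 of the 14 lists that passed at CT0 still did, with none described in the text lost, and 11, 9 and 9 lists passed at CT6, CT12 and CT18 against 10, 7 and 8; the block for lists was chosen after seeing the data. With the replicate block genotype mean gave 0, CT18 0 and the clock interaction 0, and with the replicate block within time 0, 0 and 0.

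With 1 array left out the counts ranged from 0 to 30 for genotype mean, 0 to 3 at CT0, 0 to 0 at CT6 and CT12, 0 to 5 at CT18, 0 to 4 at any time, and 0 to 1 for the interaction. They ranged from 3 to 13 for CT12 minus CT0 in control, 4 to 23 for CT18 minus CT6 in control, 0 to 63 for CT12 minus CT0 in knockout, 3 to 115 for CT18 minus CT6 in knockout, 9 to 25 for time in control and 4 to 74 for time in knockout. Clock genes over the list alone ranged from 5 to 7 for genotype mean, 12 to 14 and 9 to 11 for time in control and knockout, and 0 to 1 for the interaction. Lists ranged from 9 to 14, 31 to 45, 16 to 22 and 24 to 31, and the amplitude ratio from -0.60 to -0.32. The genotype count was 30 without knockout CT12 replicate 1, 18 without knockout CT18 replicate 3, 12 without control CT18 replicate 3, 8 without knockout CT0 replicate 2, 1 without knockout CT0 replicate 3 and 0 without all others except control CT12 replicate 1; the first 3 of these arrays are among the 4 on the other genotype's side. Time in knockout gave 74 without CT18 replicate 2, 27 without CT0 replicate 3, 22 without CT12 replicate 3, 9 without CT12 replicate 1, 6 without CT18 replicate 1 and 4 without CT0 replicate 1. CT12 minus CT0 in knockout gave 63 without CT0 replicate 3 and 0 without CT0 replicate 1, and CT18 minus CT6 in knockout 115 without CT18 replicate 2. Without knockout CT0 replicate 2, CT18 minus CT6 in control gave 23 and time in control 25.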

Other observations

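The mesothelium and patterning lists were added after the data were seen; the splits of the arrays were chosen before the results they test were seen.

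Several metabolic and stress groups did not pass for the mean genotype difference. Thermogenic adipocyte genes had a median of -0.06 (camera adjusted p = 0.349), lipolysis and lipid droplet genes -0.02 (camera adjusted p = 0.53), and fatty acid oxidation genes -0.01 with camera pointing up (adjusted p = 0.837). Inflammatory cytokine genes had a median of 0.0032 with a mean of -0.01 (adjusted p = 0.722), and unfolded protein response genes 0.04 with a mean of -0.01 (adjusted p = 0.638). Mast cell genes fell from CT6 to CT18 in knockout fat with a median of -0.28 (camera adjusted p = 2.82e-05, and adjusted p = 0.163 with an estimated correlation). Kit (-0.53 ± 0.10), Cma1 (-0.37 ± 0.11), Mcpt4 (-0.70 ± 0.22) and Cpa3 (-0.41 ± 0.17) passed over the list alone. In control fat that list had a median of -0.10, which went to between -0.05 and -0.19 with 1 array left out, and Kit fell by 0.67 (SE 0.10) over all genes (camera adjusted p = 0.00734, and adjusted p = 0.444 with an estimated correlation). The heat shock gene Hsph1 rose from CT6 to CT18 in control fat by 0.66 ± 0.16 over its list alone (list camera adjusted p = 0.00612, and adjusted p = 0.444 with an estimated correlation).

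Mesothelial genes covaried within groups: over 12 genes the mean pairwise correlation was 0.46, at percentile 100 of 10000 random lists, whose median was 0.055. For 6 subcutaneous patterning genes it was 0.10, at percentile 89.77. The random lists were matched on expression level alone and do not mark a cell type, and no other marker list was compared in this way. The percentile therefore does not set mesothelium apart from other cell types. The mesothelial list had mean log2 levels of 8.07 to 8.86 on single arrays, above the median gene level of 6.50. The patterning list had 5.70 to 6.28. Mesothelium covers visceral and not subcutaneous depots. No array of known visceral fat was there for comparison, so these values do not decide whether visceral fat was among the samples.

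Regrouping the arrays shows how often chance alone gives as much. For time in control only the real split of 100 gave 12 genes or more (highest other 6), so chance is argued against. For time in knockout 3 of 100 splits gave 14 or more, with 33 in the highest other, so a regrouping can call more genes than the real times. What set that split apart was not tested. For genotype at any time and for the interaction the real count was 0 by limma and the highest other 1, so that all 100 splits give as many whatever the data and nothing is decided (783 and 595 genes at an unadjusted p under 0.05). By camera, 39 of 100 splits gave 9 lists or more for the mean genotype difference (highest other 18). Further, 10 of 100 gave 39 or more for genotype at each time (highest other 42) and 25 of 100 gave 20 or more for time in control (highest other 32), so chance is not excluded for these list counts. For lists over time in knockout 2 of 100 gave 28 or more (highest other 31).

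The 10 splits of 3 arrays against 3 are too few for a share under 0.05. The real count and the highest other were 0 and 15 for genotype at CT0, 0 and 0 at CT6, 0 and 4 at CT12 and 1 and 1 at CT18, where 3 splits gave as many; limma gave 1106, 752 and 497 genes at an unadjusted p under 0.05 for the counts of 0. At CT0 a split that was not by genotype thus called 15 genes where genotype called 0, and what set it apart was not tested. They were 8 and 0 for CT12 minus CT0 in control, 12 and 1 for CT18 minus CT6 in control, 19 and 1 for CT12 minus CT0 in knockout and 4 and 0 for CT18 minus CT6 in knockout.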
